A study of Mus musculus with 9 samples.

How the data were processed

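Gene expression was measured by sequencing polyadenylated RNA from placental labyrinths of C57Bl/6J mice at E14.5. Per the labels' protocols, 2 randomly chosen placentas of a litter were microdissected and their labyrinths pooled, RNA was isolated with Trizol and a column kit, and 1 ug of RNA went into each library by a standard Illumina preparation. ABX dams received neomycin, vancomycin and metronidazole by gavage with ampicillin in the drinking water for a week, and neomycin, vancomycin and ampicillin in the water from breeding until E14.5. The groups were taken from the sample titles, 3 libraries each of SPF, GF and ABX. No label numbers the litters or dams, so p-values measure the spread between these 3 pools per group.

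The authors deposited raw counts per gene for each library, and per the submitters' processing notes HTSeq, DESeq2 and the mm10 build were used. The aligner, the annotation, the versions and whether counting kept the strand are not given in the sources used here. Each count file lists the same 11210 genes, and every listed gene has at least 1 count in each of the 9 libraries. A gene with no count in 1 or more of these libraries is thus not listed, even where a whole group lacks it. This leaves out low immune transcripts and 3 of the 4 Y-linked genes sought, and it limits what can be said of absent genes. Rows that name no gene were kept out of library sizes and tests. Counts in no annotated feature made up 23.8% to 29.1% of a file's total, and ambiguous counts 0.506% to 0.586%. The authors also deposited a table of log2 values for all 9 libraries. Its values equal log2 of count divided by a size factor plus 1 to within rounding, and it was used in an alternative test.

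Counts assigned to genes ranged from 485565 to 1501737 per library. The nuclear gene Gm42418, which overlaps ribosomal RNA sequence, took 2.32% to 6.06% of these counts and the mitochondrial ribosomal RNA genes 1.55% to 2.96%. Intervals given for shares of counts are exact 95% binomial (Clopper-Pearson) intervals, which cover counting error only. Gene symbols and GRCm38 coordinates come from GENCODE M21, and 11198 of 11210 identifiers matched a symbol.

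Genes were kept by edgeR's filterByExpr with the groups given (minimum count 10, minimum total 15), which left 9493 genes and removed 1717. Library sizes were scaled by TMM, and CPM values are counts over the TMM-scaled library size in units of 1e6 counts. All 9 libraries were fitted with a mean per group, with no covariate, by edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation and glmQLFTest), and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The common biological coefficient of variation was 0.174. The comparisons were GF against SPF, ABX against SPF, GF against ABX, and the mean of GF and ABX against SPF, and glmTreat tested for changes beyond 1.5-fold. The fit uses the quasi-likelihood method that is the default of this edgeR version; the choice between it and the bias-adjusted method of the same version was settled after the results of both had been seen, and both called the same genes.

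A set of 36 gene lists covering labyrinth cell types, neighbouring tissues, blood and immune cells, metabolism, transport, signalling and growth was tested with camera (limma 3.58.1) on voom values, at a preset correlation of 0.01 and at an estimated one, and with fry. Adjusted p-values run over the 33 lists with at least 3 genes tested, and the Y-linked, neutrophil and lymphocyte lists had fewer. Camera tests a list against the other genes, and fry tests whether a list's genes move on balance. Fry called 0 lists in each of the 4 comparisons, with lowest adjusted p-values of 0.851, 0.671, 0.545 and 0.935, and its test for change in either direction also called 0. The genes named follow a rule fixed before the data were examined: since fewer than 5 genes passed in each comparison, the 10 genes with the lowest p, Xist and the Y-linked genes, 8 genes chosen for the tissue and the question, and up to 4 members with the lowest adjusted p of each list described. Il2rb, Phlda2, Prl8a2, Pparg and Gm21887 fall outside the rule and were named after their values were seen.

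The gene tests of edgeR, DESeq2 and limma-voom and the list test of camera were tested on simulated data for GF against SPF, ABX against SPF and GF against ABX, while glmTreat, fry and the mean of GF and ABX were not. Counts were drawn for the 9493 genes from the means, dispersions and library sizes of the real libraries with 200 genes changed. For GF against SPF, edgeR recovered 8.4% of genes changed 1.5-fold, 42.8% changed 2-fold, 80.0% changed 3-fold and 93.2% changed 4-fold, and 6.81% of its calls were false. For GF against ABX it recovered 9.6%, 49.6%, 80.4% and 92.4%, with 3.81% false, and for ABX against SPF 6.62% of calls were false. A list shifted 1.5-fold was called in 5 of 5 simulations of each comparison at either correlation, and of 160 unshifted lists the preset correlation called 0, 0 and 3 for GF against SPF, ABX against SPF and GF against ABX. Genes were drawn independently of each other, while the real cell cycle list had an estimated correlation of 0.48 in ABX against SPF. The simulations therefore cannot show how often the preset correlation calls unshifted lists whose genes move together. In the real libraries, splits of a comparison's libraries that mixed the groups also gave list calls at the preset correlation. The highest counts were 12, 7 and 12 lists for GF against SPF, ABX against SPF and GF against ABX. The real groups gave 4, 4 and 11. Counts differed by 1.68 to 5.93 chi-square units per degree of freedom in the 9 pairs of libraries of the same group and by 1.86 to 8.60 in the 27 pairs across groups, so no library was a second copy of another.

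Alternatives fixed before the data were examined were DESeq2 1.42.0 and limma-voom as tools, DESeq2 size factors, no low-count filter and a filter at a mean of 5 CPM, leaving out each library, the replicate number as a block, a fit of only the groups compared, covariates for Y-linked expression and for junctional zone markers, haemoglobin genes left out, limma-trend on the deposited log2 table, other fold thresholds, and an estimated correlation in camera. Alternatives added after seeing the data were a covariate for the embryonic share of beta globin counts, ribosomal RNA genes left out, and the bias-adjusted quasi-likelihood method. The replicate numbers do not pair the libraries by any label, so the block is only an alternative.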

Results

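RNA sequencing was used to measure gene expression in the mouse placental labyrinth, the zone where maternal and fetal blood exchange gases and nutrients, at E14.5 of C57Bl/6J pregnancies. The dams differed in their gut microbes. Conventionally colonized dams kept under specific pathogen-free conditions (SPF) were set beside germ-free dams (GF) and dams given antibiotics before mating and through gestation (ABX). The series title names the question, whether a mother's microbes bear on how the placenta develops. Each group held 3 libraries, and per the protocols each library pooled the labyrinths of 2 placentas from a litter. Counts assigned to genes came to 485565, 842282 and 889897 in SPF replicates 1 to 3, to 1501737, 1313274 and 576992 in GF, and to 808311, 619029 and 633812 in ABX. At this depth 9493 genes were tested.

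Sex-linked transcripts separated the pools. Xist, the RNA that silences an X chromosome in female cells, stood at 1436 CPM in GF replicate 1, 1594 in GF replicate 2 and 1683 in ABX replicate 2. Ddx3y, a Y-linked RNA helicase, stood at 3.23, 2.93 and 3.30 CPM there. In the other 6 libraries, all 3 SPF libraries among them, Xist lay between 49.9 and 93.3 CPM and Ddx3y between 115 and 168 CPM. No library lay between these levels, although each is described as a pool of 2 randomly chosen placentas. Xist was high in none of the SPF libraries, so sex was not balanced over the groups. Libraries of the same group were correlated at a mean r of 0.932 across genes and those of different groups at 0.929. ABX replicate 1 had the lowest mean correlation with the other libraries, 0.909 against at least 0.919 for any other library.

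**Figure D1:**
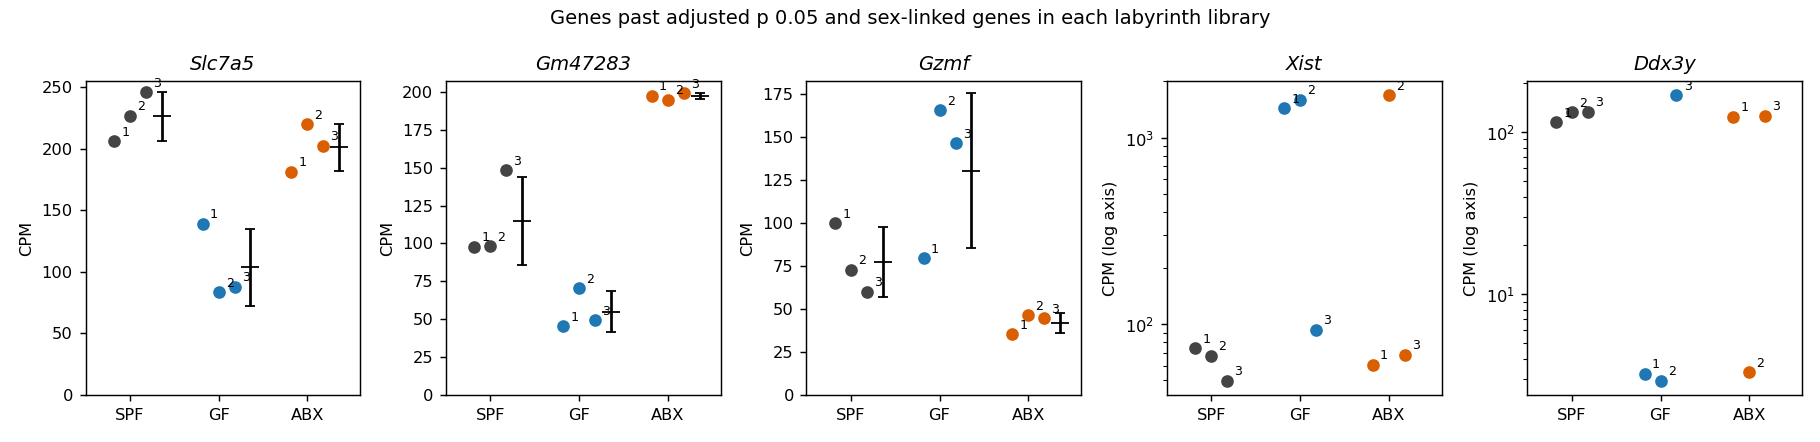
CPM of the 3 genes past an adjusted p of 0.05, Slc7a5 (GF against SPF), Gm47283 and Gzmf (GF against ABX), and of the sex-linked genes Xist and Ddx3y, in each of the 9 labyrinth libraries. Points are libraries numbered by replicate, bars at the right of each group are mean and SD (n = 3), and the axes of Xist and Ddx3y are logarithmic; GF replicates 1 and 2 and ABX replicate 2 hold Xist at 1436 CPM or more, and no other library is above 93.3 CPM.

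The comparison of GF with SPF measured labyrinth expression with no maternal microbes against a conventional microbiota. The contrast was not one of microbes alone, since Xist was high in GF replicates 1 and 2 and in none of the SPF libraries. Each GF library also had a larger share of counts in no annotated feature than each SPF library. Slc7a5, which encodes the LAT1 transporter of large neutral amino acids, was lower in GF, at 103 ± 30.9 CPM against 226 ± 19.9 CPM (SD, n = 3 each). The log2 fold change was -1.11 (SE 0.19, 95% interval -1.50 to -0.72, edgeR adjusted p = 0.030), a 2.16-fold decrease. Each GF library lay below each SPF library. Slc7a5 (ENSMUSG00000040010) is a protein-coding gene on chromosome 8, from 121881150 to 121907694 of GRCm38, and was the only gene past the threshold in this comparison. ABX labyrinths held 201 ± 19.3 CPM of Slc7a5 (SD, n = 3), a log2 fold change of -0.18 against SPF (SE 0.19, edgeR adjusted p = 0.840), and the direct test of GF against ABX gave -0.93 (SE 0.19, edgeR adjusted p = 0.0858), which did not pass. That difference passed with the embryonic globin share as a covariate (-1.12, edgeR adjusted p = 0.0162), without GF replicate 1 (-1.23, 0.0034) and without ABX replicate 1 (-0.99, 0.0216).

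The genes next in rank for GF against SPF did not pass the threshold. Ramp3, an accessory protein of adrenomedullin receptors, was at 64.1 ± 22.5 CPM in GF and 25.4 ± 1.75 CPM in SPF (SD, n = 3 each), with a log2 fold change of 1.3 and an edgeR adjusted p of 0.487, and passed without GF replicate 1 (1.59, edgeR adjusted p = 0.0204). Wdfy1 (1.47), Wfdc1 (1.79), the arginine methyltransferase gene Prmt1 (1.21) and Emc9 (1.37) had positive log2 fold changes. Gm47283 (-1.06), the glycosylation enzymes Man1c1 (-0.81) and Mgat4b (-0.57) and Prl7d1 (-0.60), a placental hormone of the prolactin family, had negative values. The edgeR adjusted p of these 8 genes lay between 0.199 and 0.999. Of the genes fixed for this tissue, the monocarboxylate transporter gene Slc16a1 was at 507 ± 36.7 CPM in GF and 406 ± 31.4 CPM in SPF (SD, n = 3 each), with a log2 fold change of 0.32 (SE 0.15, edgeR adjusted p = 0.999). Values for the vascular growth factors and receptors were 0.19 for Vegfa, 0.33 for Pgf, -0.18 for Flt1 and -0.05 for Kdr, and -0.12 for the fetal growth factor Igf2, each with an edgeR adjusted p of 0.999. The fatty acid receptor genes Ffar2 and Ffar3 were not analysed here.

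Of 33 gene lists tested in GF against SPF, 4 passed camera at a preset correlation of 0.01. Each of the 10 splits of the GF and SPF libraries, the real one included, gave at least 4 lists, so chance cannot be excluded for this count. Cell cycle genes were higher, with 24 of 28 members above 0 and a median log2 fold change of 0.36 (camera adjusted p = 0.0045, and 0.722 with an estimated correlation). Among them were Cenpf (0.99), Ccnb2 (1.38) and Top2a (0.62). No member passed edgeR's test over all genes or adjusted over the list alone. The uterine natural killer cell list was higher, with a median of 0.67 over 6 members (camera adjusted p = 0.0045, and 0.722 with an estimated correlation). Only 6 of the list's 12 members were measured. The 5 granzyme genes in it carried that shift, with log2 fold changes of 0.86 for Gzmc, 0.77 for Gzmf and 0.70 for Gzmg, and the cytokine receptor gene Il2rb was at -0.23. Of the list 1 member passed when adjusted over the list alone and 0 over all genes. Markers of the maternal decidua lay above 0 in 9 of 9 members, with a median of 0.26 that did not pass (camera adjusted p = 0.118). Markers of sinusoidal trophoblast giant cells, which line the maternal blood spaces, were lower, with a median of -0.33 over 5 members and values of -0.42 for Ctsq and -0.34 for Prl3b1 (camera adjusted p = 0.014, and 0.722 with an estimated correlation). Erythroid genes were lower, with a median of -0.27 over 10 members (camera adjusted p = 0.014, and 0.722 with an estimated correlation). Of its members 3 were above 0, the embryonic globin gene Hbb-bh1 at 0.83 among them. With an estimated correlation no list passed.

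Lists for other functions did not pass in GF against SPF. The median of the angiogenic signalling list was 0.04 over 23 genes (camera adjusted p = 0.828), and that of nutrient and ion transporters -0.0019 over 29 genes (camera adjusted p = 0.935). That of the interferon response was 0.15 over 18 genes (camera adjusted p = 0.184). All 4 measured genes for sensing and use of short-chain fatty acids lay above 0, with a median of 0.25 (camera adjusted p = 0.184). The medians of the 29 lists that did not pass lay between -0.65, for yolk sac endoderm, and 0.29. By edgeR 317 genes had an unadjusted p under 0.05, where 475 are expected by chance. The test against a 1.5-fold change passed 0 genes. The Slc7a5 call ended with limma-voom (adjusted p = 0.0651), and with Y-linked expression as a covariate (0.119). It also ended without SPF replicate 1 (0.0637), 2 (0.263) or 3 (0.773), GF replicate 2 (0.521) or 3 (0.723), or ABX replicate 2 (0.0623). The log2 fold change lay between -1.41 and -0.95 in every alternative. Without GF replicate 2 the cell cycle median was -0.05 (camera adjusted p = 0.453). The natural killer (median 0.51, adjusted p = 0.117), giant cell (-0.10, 0.409) and erythroid lists (-0.02, 0.281) did not pass either. Erythroid genes also failed to pass without SPF replicate 3 (-0.11, 0.216) or with the Y-linked covariate (-0.12, 0.413). The cell cycle median was 0.13 with the embryonic globin share as a covariate (camera adjusted p = 0.0268) and 0.62 without GF replicate 1, where the erythroid median was -0.50.

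**Figure D2:**
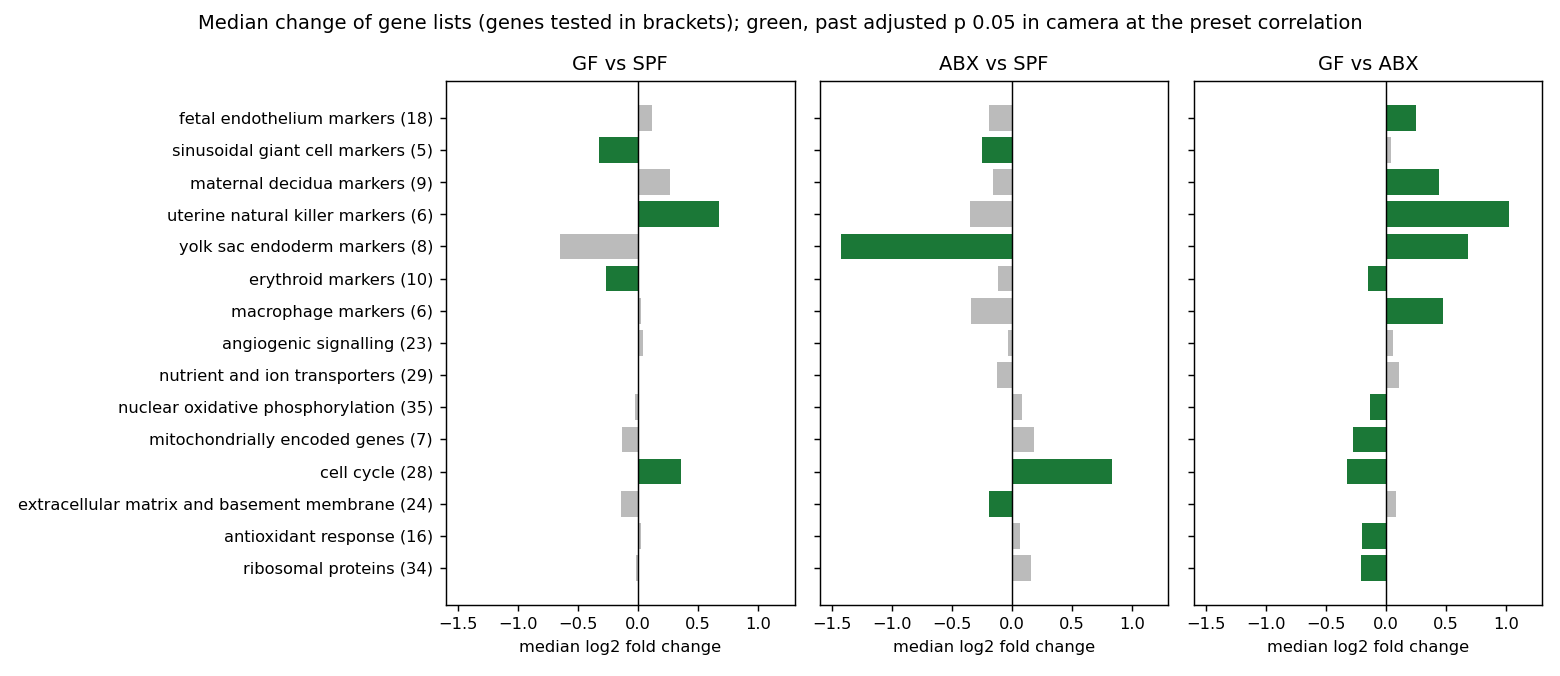
Median log2 fold change (horizontal axis) of the 13 gene lists past an adjusted p of 0.05 in at least 1 comparison, and of the angiogenic and transporter lists, for GF against SPF, ABX against SPF and GF against ABX; the number of genes tested is in brackets. Green bars passed camera at the preset correlation and grey bars did not; the cell cycle bar stands at 0.36, 0.83 and -0.32, and no bar passed with an estimated correlation.

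The comparison of ABX with SPF measured labyrinth expression in dams given antibiotics against a conventional microbiota. No microbial load is given in the sources used here, and effects of the drugs themselves cannot be told apart from loss of microbes. Cell cycle genes were higher in ABX, with all 28 measured members above 0 and a median log2 fold change of 0.83 (camera adjusted p = 6.92e-12, and 0.640 with an estimated correlation). The proliferation marker Mki67 stood at 74.0 ± 17.0 CPM in ABX against 24.2 ± 8.78 CPM in SPF (SD, n = 3 each), a log2 fold change of 1.57. The mitotic genes Ccna2 (1.59), Ube2c (1.01) and Cdk1 (0.90) had values in the same direction. Of the 28 members 8 passed when adjusted over the list alone and 0 over all genes tested. The share of embryonic globins, which fall as definitive red cells replace primitive ones, differed alongside. Hbb-y and Hbb-bh1 made up 44.9% ± 8.22 of beta globin counts in ABX, 27.2% ± 4.54 in SPF and 33.0% ± 21.2 in GF (SD, n = 3 each). Each ABX library lay above each SPF library (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows).

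**Figure D3:**
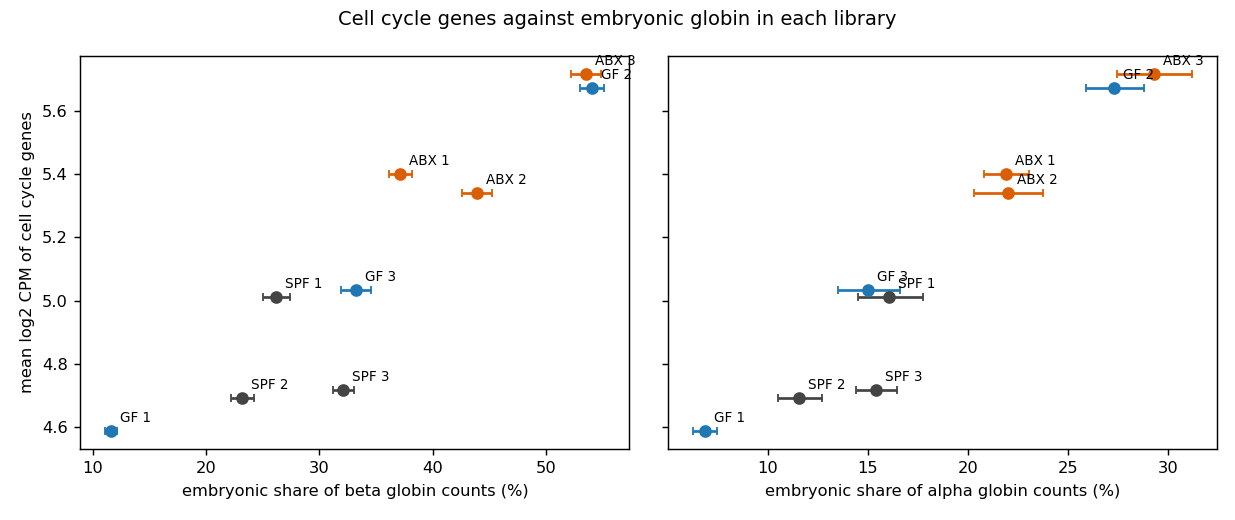
Mean log2 CPM of the cell cycle genes (vertical axis) against the embryonic share of beta globin and of alpha globin counts in percent (horizontal axes) in the 9 libraries, with each point a library and bars of 95% exact binomial intervals. GF replicate 1 has the lowest beta share, 11.6% (11.1 to 12.1), and GF replicate 2 the highest, 54.1% (53.0 to 55.2).

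Markers of yolk sac endoderm, a tissue outside the labyrinth, were lower in ABX than in SPF, with 8 of 8 members below 0 and a median of -1.43 (camera adjusted p = 1.04e-04, and 0.640 with an estimated correlation). The apolipoprotein gene Apoa2 stood at 6.73 ± 1.98 CPM in ABX and 29.7 ± 26.4 CPM in SPF (SD, n = 3 each). The genes Apob (-1.73), Apoa4 (-1.47) and Ttr (-1.38) had negative log2 fold changes. Of the list 2 members passed when adjusted over the list alone and 0 over all genes. The difference rested on SPF replicate 3, without which the median was -0.24 (camera adjusted p = 0.277). Sinusoidal giant cell markers were lower by a median of -0.25 over 5 members, with -0.75 for Lepr and -0.58 for Ctsq (camera adjusted p = 0.0315, and 0.640 with an estimated correlation). Genes of the extracellular matrix and basement membrane had a median of -0.19, with 18 of 24 members below 0 and values of -0.63 for Timp3, -0.58 for Col5a2 and -0.34 for Col1a2 (camera adjusted p = 0.0221, and 0.640 with an estimated correlation).

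No single gene passed in ABX against SPF. The gene first in rank was Ncapd2, a condensin subunit that compacts mitotic chromosomes, at 138 ± 23.7 CPM in ABX and 56.8 ± 8.25 CPM in SPF (SD, n = 3 each), with a log2 fold change of 1.31 (SE 0.25, edgeR adjusted p = 0.187). Rpl41 (1.02), Banf1 (0.96), Cotl1 (0.87), Gpsm3 (1.37) and Palm (1.22) had positive values and Mirt1 (-1.27), Samd4 (-1.19) and Tmem87b (-0.80) negative values, with edgeR adjusted p between 0.246 and 0.338. Values of the fixed genes were 0.22 for Slc16a1, 0.30 for Vegfa, 0.69 for Pgf, -0.26 for Flt1, -0.34 for Kdr and 0.15 for Igf2, with edgeR adjusted p between 0.669 and 0.865. The angiogenic list had a median of -0.03 (camera adjusted p = 0.301), the fetal endothelium list -0.19 (0.0690). The medians were -0.12 for nutrient transporters (0.226) and -0.16 for the hypoxia response (0.0876). The 29 lists that did not pass had medians between -0.35 and 0.24.

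The edgeR test called 0 genes in ABX against SPF, with 719 at an unadjusted p under 0.05, where 475 are expected by chance. DESeq2 and limma-voom also called 0, with 494 and 647. By edgeR the same ABX and SPF libraries split in other ways gave 357 to 692 genes at an unadjusted p under 0.05. In data simulated on these libraries edgeR recovered 10.4% of genes changed 1.5-fold, 48.8% of those changed 2-fold and 90.8% of those changed 4-fold in this comparison. With only ABX and SPF libraries in the fit 2 genes passed, Ncapd2 (edgeR adjusted p = 0.0463) and Phlda2. Ncapd2 also passed without GF replicate 1 (0.0287) or 2 (0.0473), Rpl41 without ABX replicate 2 (0.0431) and Palm without ABX replicate 3 (0.0308). The giant cell list did not pass without SPF replicate 1 (median -0.205, camera adjusted p = 0.0597) or 3 (-0.29, 0.0723) or ABX replicate 2 (-0.24, 0.0746) or 3 (-0.17, 0.333). The matrix list did not pass without SPF replicate 1 (-0.20, 0.0586) or 2 (-0.12, 0.0787) or ABX replicate 2 (-0.23, 0.0787) or 3 (-0.15, 0.333), nor with the Y-linked covariate (-0.18, 0.0715). With the embryonic globin share as a covariate the giant cell (-0.01, 0.835) and matrix (-0.09, 0.108) lists did not pass. With the globin covariate the cell cycle median was 0.31 (camera adjusted p = 0.0044). The cell cycle list passed without each of the 9 libraries at the preset correlation, and did not pass with an estimated one (camera adjusted p = 0.640).

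The comparison of GF with ABX set both routes meant to remove maternal microbes side by side. Gzmf, a granzyme gene of the cluster on chromosome 14 that natural killer cells of the pregnant uterus express, was higher in GF, at 131 ± 45.2 CPM against 42.1 ± 5.81 CPM in ABX (SD, n = 3 each). The log2 fold change was 1.62 (SE 0.27, 95% interval 1.06 to 2.19, edgeR adjusted p = 0.016). The protein-coding gene Gm47283, annotated on the Y chromosome, was lower in GF, at 55.0 ± 13.4 CPM against 197 ± 2.15 CPM (SD, n = 3 each). The log2 fold change was -1.82 (SE 0.21, 95% interval -2.26 to -1.39, edgeR adjusted p = 2.89e-05). It was the 1 gene past a test against a 1.5-fold change. SPF labyrinths held 77.6 ± 20.4 CPM of Gzmf and 115 ± 29.1 CPM of Gm47283 (SD, n = 3), and neither gene passed in GF or in ABX against SPF. Gm47283 in GF against SPF passed with the globin covariate (-1.16, edgeR adjusted p = 0.0232) and without ABX replicate 1 (-1.06, 0.0312).

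Gzmf (ENSMUSG00000015441) lies from 56205263 to 56211417 of GRCm38 on the minus strand and overlaps the antisense gene Gm4022. Since no source used here states whether the counting kept the strand, its counts could include antisense reads. Gm47283 (ENSMUSG00000096768) lies from 90784738 to 90816464 on the Y chromosome. A transcript of 887 nt is matched over 86.5% of its length at 95% identity or more by Gm21887, an X-linked gene not analysed here, so its counts are uncertain. Its level did not follow the Y-linked gene Ddx3y, since ABX replicate 2 held 195 CPM of Gm47283 and the other ABX libraries 198 and 199 CPM.

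The natural killer list was higher in GF than in ABX at the preset correlation, with a median log2 fold change of 1.03 (camera adjusted p = 3.48e-04, and 0.632 with an estimated correlation). Of its 12 members 6 were measured, the 5 granzyme genes above 0 and Il2rb below. Members stood at 1.65 for Gzmd, 1.29 for Gzme and 0.76 for Gzmg beside Gzmf and -0.31 for Il2rb. Of the list 4 members passed when adjusted over the list alone and 1 over all genes. Maternal decidua markers lay above 0 in 9 of 9 members, of which 2 passed when adjusted over the list alone and 0 over all genes, with a median of 0.44 (camera adjusted p = 0.0141, and 0.632 with an estimated correlation), 1.76 for the steroid enzyme gene Hsd11b1 and 0.58 for Cryab. Macrophage markers had a median of 0.47 with 6 of 6 members above 0 (camera adjusted p = 0.0310, and 0.632 with an estimated correlation), 0.47 for Cd68 and 1.17 for Cx3cr1. Cx3cr1 was low in ABX, at 12.7, 1.65 and 3.19 CPM in replicates 1 to 3. Fetal endothelium markers had a median of 0.24 with 14 of 18 above 0 (camera adjusted p = 0.0078, and 0.632 with an estimated correlation), 0.62 for Ptprb and 0.68 for Emcn. Yolk sac endoderm markers had a median of 0.68 with 7 of 8 above 0 (camera adjusted p = 0.0141, and 0.693 with an estimated correlation).

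Of the lists lower in GF than in ABX at the preset correlation, cell cycle genes had a median of -0.32 with 24 of 28 members below 0 (camera adjusted p = 5.69e-05, and 0.655 with an estimated correlation), including Mki67 (-0.87) and Cdc20 (-0.77). Ribosomal protein genes had a median of -0.21 with 28 of 34 below 0 (camera adjusted p = 0.0044, and 0.702 with an estimated correlation). Mitochondrially encoded genes had a median of -0.28 with 7 of 7 below 0 (camera adjusted p = 0.0086, and 0.641 with an estimated correlation). Nuclear genes of oxidative phosphorylation had -0.14 with 25 of 35 below 0, Cox4i1 (-0.62) and Cox8a (-0.58) among them (camera adjusted p = 0.0189, and 0.693 with an estimated correlation). Antioxidant genes had a median of -0.20, with -0.41 for Txn1 (camera adjusted p = 0.0318, and 0.632 with an estimated correlation). Erythroid genes had -0.15, with -1.04 for the embryonic globin gene Hba-x (camera adjusted p = 0.0343, and 0.632 with an estimated correlation). The angiogenic list (median 0.06, camera adjusted p = 0.459) and the transporter list (0.11, camera adjusted p = 0.301) did not pass. The fixed genes had values of 0.10 for Slc16a1, -0.11 for Vegfa, -0.36 for Pgf, 0.07 for Flt1, 0.29 for Kdr and -0.27 for Igf2, with edgeR adjusted p between 0.707 and 0.956.

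By edgeR 767 genes had an unadjusted p under 0.05 in GF against ABX, where 475 are expected by chance. The same GF and ABX libraries split in other ways gave 428 to 850. The next genes in rank were Wdfy1 (1.79, edgeR adjusted p = 0.0828), Rpl41 (-0.999, 0.0858), Slc7a5, Tmem87b (0.88, 0.103), Mirt1 (1.26, 0.135), Ncapd2 (-1.06, 0.135), the pseudogene Gm10364 (-2.85, 0.135) and Angptl4, an inhibitor of lipoprotein lipase (2.12, 0.135). Gm10364 was near the floor in GF, at 0.647, 3.66 and 1.83 CPM in replicates 1 to 3. Wdfy1 passed with a fit of only the groups compared (edgeR adjusted p = 0.0490) and without SPF replicate 1 (0.0281) or ABX replicate 1 (0.0141). Rpl41 passed without ABX replicate 2 (0.0184), Ncapd2 without GF replicate 2 (0.0239), and Gzmd with the globin covariate (0.0376) and without GF replicate 1 (0.0129). Gm47283 passed in the 23 alternatives run for single genes, but 0 genes passed a test against a 2-fold change. The Gzmf call ended with limma-voom (adjusted p = 0.158), with the Y-linked covariate (0.0647), and without GF replicate 2 (0.0634) or 3 (0.192) or ABX replicate 1 (0.180), 2 (0.0700) or 3 (0.0645). Its log2 fold change lay between 1.38 and 1.91.

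Of the 11 lists the natural killer list passed without each library at the preset correlation, and did not pass with an estimated one (camera adjusted p = 0.632). The cell cycle list had a median of 0.0049 without GF replicate 1 (camera adjusted p = 0.757). The ribosomal (median -0.08, adjusted p = 0.528), antioxidant (-0.10, 0.601), oxidative phosphorylation (-0.08, 0.244), endothelium (0.13, 0.244) and macrophage lists (0.36, 0.244) did not pass without it. Without GF replicate 2 the erythroid median was 0.07 (camera adjusted p = 0.631). The decidua (0.27, 0.366), yolk sac (0.41, 0.287), mitochondrial (-0.22, 0.162) and macrophage lists (0.59, 0.0549) did not pass without it. Without ABX replicate 1 the decidua (0.35, 0.0639), yolk sac (0.55, 0.0750), erythroid (0.06, 0.426) and mitochondrial lists (-0.15, 0.0639) did not pass. Without ABX replicate 2 the yolk sac (0.87, 0.0871), macrophage (0.36, 0.356), oxidative phosphorylation (-0.09, 0.112), antioxidant (-0.23, 0.128) and ribosomal lists (-0.18, 0.127) did not. Without ABX replicate 3 the endothelium (0.13, 0.161), decidua (0.43, 0.0565), macrophage (0.49, 0.151) and erythroid lists (-0.24, 0.0863) did not, nor did oxidative phosphorylation (-0.02, 0.841), mitochondrial (-0.31, 0.0555), antioxidant (-0.14, 0.151) and ribosomal genes (-0.04, 0.923). With the globin covariate the cell cycle (-0.08, 0.453), ribosomal (-0.08, 0.437), antioxidant (-0.12, 0.437), oxidative phosphorylation (-0.07, 0.234), macrophage (0.32, 0.219) and endothelium lists (0.20, 0.129) did not pass. Erythroid genes did not pass with the Y-linked covariate (-0.09, 0.0633), with which the endothelium median was 0.11 (camera adjusted p = 0.0196). Other medians moved further from 0 and passed. The cell cycle median was -0.84 without GF replicate 2, that of decidua 0.75 without GF replicate 1 and that of mitochondrial genes -0.43 without GF replicate 3. Without ABX replicate 1 the macrophage median was 0.79 and the ribosomal median -0.39. The yolk sac median was 1.12 with the globin covariate and 1.05 without ABX replicate 3, and the erythroid median -0.49 with the globin covariate, -0.42 without GF replicate 1 and -0.37 without ABX replicate 2.

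The mean of GF and ABX was compared with SPF to ask which genes differed on average over both routes meant to deplete maternal microbes. A gene changed under 1 route alone can be missed, and effects of opposite sign cancel. Gzmf and Gm47283, with opposite signs in GF and ABX against SPF, had edgeR unadjusted p-values of 0.855 and 0.416 here. The edgeR test called 0 genes, with 435 at an unadjusted p under 0.05, where 475 are expected by chance, and DESeq2 and limma-voom called 0, with 258 and 414. At the level of lists, cell cycle genes were higher, with 27 of 28 members above 0 and a median of 0.57 (camera adjusted p = 8.57e-10, and 0.747 with an estimated correlation). Yolk sac endoderm (-1.01, camera adjusted p = 1.86e-04), sinusoidal giant cell (-0.29, 0.0040) and matrix genes (-0.15, 0.0053) were lower, each with an adjusted p of 0.747 with an estimated correlation. Without SPF replicate 3 the yolk sac median was -0.01 (camera adjusted p = 0.958), and the matrix list did not pass without SPF replicate 1 (-0.11, 0.0574) or 2 (-0.15, 0.0705) or ABX replicate 3 (-0.14, 0.0642). It did not pass with the Y-linked (-0.14, 0.129) or globin covariate (-0.13, 0.0524) either, nor did the giant cell list with the globin covariate (-0.16, 0.224), where the cell cycle median was 0.28 (0.0034). Without GF replicate 2 the cell cycle median was 0.35 (camera adjusted p = 8.04e-06).

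No gene passed in both GF and ABX against SPF by edgeR, and 70 genes had an unadjusted p under 0.05 in both with the same sign, 42 higher and 28 lower. Both comparisons use the same SPF libraries. In 20 simulations all 9 libraries, SPF included, were drawn from common gene means, with genes independent of each other. These gave 99.2 genes shared in this way on average, with 79 to 122. At an unadjusted p under 0.05 they gave 462 genes per comparison on average, against 317 for GF and 719 for ABX observed. The deviations of the real SPF libraries are therefore not part of the simulated values. Independent lists of the observed lengths would share 7.67 higher and 4.53 lower genes. Because the SPF libraries are shared, that is not a valid baseline here. The 70 shared genes lay below the lowest simulated count of 79, so they were no excess over the simulations. Across genes, which are not independent replicates, the log2 fold changes of the GF and ABX comparisons were correlated at r = 0.461 with a covariance of 0.0557, against 0.524 and 0.0589 on average in the simulations, so the covariance lay 0.0032 below the simulated value. The lowest simulated values were 0.504 and 0.0559. With 3 SPF libraries the controls could not be split.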

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

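The GF-colony question, the relation to the decidua score and the choice of Gm47283 for a search of shared transcripts were tests chosen only after the result was seen, while the Y-linked covariate and the omission of each library were planned and put to these explanations afterwards. Gm47283 was singled out because the GF and ABX effects on it differed in the direct test, by a log2 value of -1.82. Sex of the pooled placentas was argued against, since the value with Y-linked expression as a covariate was -1.84 and ABX replicate 2, with Xist at 1683 CPM, held 195 CPM of Gm47283 beside 198 and 199 in the other ABX libraries. Shared reads stay open, because 86.5% of a transcript is matched by the X-linked gene Gm21887, which is not analysed here. A variant carried by the germ-free colony may also account for it and was not tested by sequence. ABX against SPF had a log2 fold change of 0.76 (SE 0.20, edgeR adjusted p = 0.338), which leaves open whether GF alone departs. In GF against SPF the value was -1.06 (edgeR adjusted p = 0.199), and it passed with the globin covariate (0.0232) and without ABX replicate 1 (0.0312). A count of reads over positions that differ between Gm47283 and Gm21887, in litters of both colonies, would separate these.

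Gzmf was singled out for the same reason, with a direct difference of GF and ABX effects of 1.62, and the natural killer list, of which 6 of 12 members were measured, moved with it. A single GF or ABX library was argued against for the list at the preset correlation, since its median was at least 0.90 with any of them left out. The list did not pass with an estimated correlation (camera adjusted p = 0.632). More maternal decidua in the GF pools is a candidate explanation, since the natural killer and decidua scores were correlated within groups at r = 0.853 (exact permutation p = 0.0278, adjusted p = 0.0417 over 3 relations, 216 arrangements). Across the 9 libraries r was 0.889 (permutation p = 9.37e-04), and 0.683 without GF replicates 2 and 3, the libraries farthest out. Of the 9 decidua genes tested 1, Hsd11b1, is also in another list, and the abundant decidual hormone gene Prl8a2 had a log2 fold change of 0.32 (SE 0.52, edgeR adjusted p = 0.918), so the amount of decidua stays uncertain, and staining sections for granzyme and decidual markers would test it.

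The share of counts in no annotated feature was singled out because its mean in GF, 27.4%, came from libraries that each lay above each SPF library. The difference was 2.41 percentage points (exact permutation p = 0.1, the smallest that 3 against 3 allows). Each GF library also lay above each ABX library, with a difference of means of 2.64 percentage points (exact permutation p = 0.1).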

How the results depend on the processing

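The calls rest on few libraries. Among named genes 3479 comparisons with an alternative kept their call and direction, 15 lost a call, 19 gained a call and 21 turned direction. Genes that were uncalled and stayed so count among those kept. Of 23 alternatives, Slc7a5 in GF against SPF kept its call in 15 and lost it in 8. In GF against ABX, Gzmf kept its call in 16 and lost it in 7, and Gm47283 kept its call in 23. Among called lists 237 kept the call and direction, 80 lost the call and 4 had a median of the other sign. In 1 more, yolk sac endoderm in depleted against SPF, only camera's direction turned. In GF against SPF limma-voom called 0 genes, the Y-linked covariate 0 and the embryonic globin covariate 2. In ABX against SPF a fit of only the groups compared called 2. In GF against ABX limma-voom called 1, the Y-linked covariate 1 and the globin covariate 6, and a fold threshold of 1.2 gave 2 genes and a threshold of 2 gave 0. With an estimated correlation camera called 0 lists in GF against SPF, 0 in ABX against SPF, 0 in GF against ABX and 0 in depleted against SPF; with the globin covariate it called 7 in GF against SPF and 5 in GF against ABX. The cause was not tested.

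With 1 library left out, genes called ranged from 0 (without SPF replicate 1) to 5 (without GF replicate 1) in GF against SPF, from 0 (without SPF replicate 1) to 2 (without GF replicate 2) in ABX against SPF and from 1 (without GF replicate 3) to 9 (without GF replicate 1) in GF against ABX, and were 0 throughout in depleted against SPF and in both. Lists ranged from 3 (without GF replicate 2) to 11 (without GF replicate 3), from 2 (without SPF replicate 3) to 12 (without ABX replicate 1), from 3 (without ABX replicate 3) to 12 (without GF replicate 3) and, in depleted against SPF, from 3 (without SPF replicate 2) to 10 (without ABX replicate 1). List medians ranged from -0.051 (without GF replicate 2) to 0.62 (without GF replicate 1) for cell cycle in GF against SPF, from -0.84 (without GF replicate 2) to 0.0049 (without GF replicate 1) for cell cycle and from -0.42 (without GF replicate 1) to 0.069 (without GF replicate 2) for erythroid genes in GF against ABX, where it was 0.061 without ABX replicate 1, and from -1.42 (without SPF replicate 2) to -0.015 (without SPF replicate 3) for yolk sac endoderm in depleted against SPF.

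Values of uncalled genes that turned direction were, for GF against SPF, Pgf -0.54 (without GF replicate 2) to 0.83 (without GF replicate 1), -0.070 without SPF replicate 3 and -0.15 with the globin covariate; Vegfa -4.98e-04 (without GF replicate 3) to 0.30 (without GF replicate 1); Igf2 -0.21 (without GF replicate 3) to 0.0072 (without SPF replicate 1); Kdr -0.15 (without GF replicate 2) to 0.059 (without GF replicate 3), and 0.020 without SPF replicate 1. Lepr ranged from -0.77 (without GF replicate 1) to 0.077 (without GF replicate 2), Hbb-bh1 from -0.57 (without GF replicate 2) to 1.39 (without GF replicate 1), with -0.0029 under the globin covariate, and Hbb-bt from -0.64 (without GF replicate 1) to 0.058 (without GF replicate 2). For ABX against SPF the globin covariate gave -0.076 for Pgf and 0.063 for Prl3b1, and the Y-linked covariate 0.028 for Ddx3y. For GF against ABX Pgf ranged from -1.23 (without GF replicate 2) to 0.14 (without GF replicate 1), Vegfa from -0.30 (without ABX replicate 3) to 0.027 (without ABX replicate 2), with 0.0027 without GF replicate 1, Flt1 from -0.16 (without GF replicate 3) to 0.22 (without GF replicate 1), Lyve1 from -0.082 (without GF replicate 1) to 0.67 (without GF replicate 3) and mt-Nd6 from -1.35 (without GF replicate 1) to 0.91 (without ABX replicate 1), and Alas2 was -0.0083 with the globin covariate.

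With the replicate number as a block, edgeR called 1, 0, 3 and 0 genes in GF against SPF, ABX against SPF, GF against ABX and depleted against SPF, Wdfy1 the gene added (edgeR adjusted p = 0.0401), and camera called 5, 6, 9 and 4 lists. In GF against ABX the block ended the calls of the erythroid and antioxidant lists (camera adjusted p = 0.0512 each). Pairing by number had little in the data: 0 of 9 same-number pairs had r above 0.1 after group means were removed, and 2 of 9 libraries were best correlated with their own number.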

Other observations

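The relations of scores to embryonic globin shares, the globin covariate and the look at genes listed apart in the deposited table were tests chosen only after the result was seen. The splits, the omission of each library and the Y-linked covariate were planned, and the last pair were put to the cell cycle genes as explanations after their shift was seen. Cell cycle expression followed the embryonic globin share library by library. The mean of the cell cycle genes was correlated with the embryonic share of alpha globin counts, Hba-x among the alpha globins, at r = 0.968 over the 9 libraries (permutation p = 4.41e-05, adjusted p = 1.32e-04 over 3 relations) and at 0.974 within groups (permutation p = 0.00926, adjusted p = 0.0278). For the beta share r was 0.927 (permutation p = 4.30e-04), and 0.907 within groups (permutation p = 0.0694, adjusted p = 0.0694), which did not pass. The r without the 2 libraries farthest out was 0.926 for alpha and 0.889 for beta. Hba-x made up 24.4% ± 4.25 of alpha globin counts in ABX, 14.3% ± 2.42 in SPF and 16.4% ± 10.3 in GF (SD, n = 3 each).

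The deposited log2 table lists 57 genes apart from the rest, Pparg, a regulator of trophoblast differentiation, among them, and no label says why. Of the 54 tested here, 50 had an edgeR unadjusted p under 0.05 in both GF and ABX against SPF with the same sign, 24 lower and 26 higher. Another 2, Gzmf and Gm47283, had such a p in both with opposite signs. By edgeR 0 of the 54 passed the adjusted threshold in either comparison. Pparg had log2 fold changes of -0.47 in GF and -0.52 in ABX (edgeR adjusted p = 0.999 and 0.474). How they were picked is not given in the sources used here, so their direction is not independent evidence.

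Cell cycle genes were higher in ABX than in SPF at the preset correlation (camera adjusted p = 6.92e-12, and 0.640 with an estimated correlation). A single library was argued against, since the list's median was 0.82 without ABX replicate 1. With 1 library left out it was lowest without ABX replicate 3, at 0.67. Sex of the pooled placentas was argued against by a median of 0.75 with the Y-linked covariate. Litters at different developmental stages may account for part of it and cannot be told apart from treatment, because each ABX library had a higher share of embryonic globins than each SPF library. Within groups the relation to cell cycle expression passed for the alpha share (r = 0.974, permutation p = 0.00926, adjusted p = 0.0278) and did not for the beta share (r = 0.907, permutation p = 0.0694, adjusted p = 0.0694). With the beta share as a covariate the median was 0.31 (camera adjusted p = 0.0044). Whether antibiotics delayed the conceptus or litters were dissected at slightly different ages could be tested by staging embryos of the same litters by limb and weight.

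Other splits of the libraries were fitted in the same way. In GF against SPF, 4 of the 10 splits of the 6 libraries gave as many genes (real 1, highest other 10) and 10 of 10 as many lists (4, 12). In ABX against SPF, 10 of 10 gave as many genes (0, 0), which a real count of 0 fixes, and 6 of 10 as many lists (4, 7). In GF against ABX, 3 of 10 gave as many genes (2, 12) and 3 of 10 as many lists (11, 12). With 10 splits the share is never under 0.1. For depleted against SPF 100 of the 840 splits were drawn. As many lists came from 73 of 100 (real 4, highest other 11) and as many genes at an unadjusted p under 0.05 in both from 56 (70, 304), so chance cannot be excluded for these. By edgeR as many genes came from 100 of 100 (0, 43), and as many past the threshold in both from 100 (0, 11), but real counts of 0 fix both outcomes, which say nothing about chance. DESeq2 and limma-voom, like edgeR, called 0 genes at the adjusted threshold in ABX and in depleted against SPF. At an unadjusted p under 0.05 edgeR, DESeq2 and limma-voom gave 719, 494 and 647 genes in ABX against SPF and 435, 258 and 414 in depleted against SPF. The split of GF replicates 1 and 3 and ABX replicate 1 against GF replicate 2 and ABX replicates 2 and 3 gave 12 genes, and GF replicate 2 with ABX replicates 2 and 3 as the set of 3 gave up to 43. Those 3 libraries had the highest embryonic shares of beta globin counts, 54.1% (53.0 to 55.2), 43.9% (42.6 to 45.2) and 53.5% (52.2 to 54.8), so these splits point to a structure of the samples that crosses the groups.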
